A study of Homo sapiens with 2 samples.

How the data were processed

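The samples were cells of the human induced pluripotent stem cell line BU3 NGST, a line with a GFP reporter at NKX2-1. Per the labels' protocols, the cells were differentiated to NKX2-1 GFP-positive lung progenitors and replated as spheres in an airway (proximal) or an alveolar (distal) medium. Airway spheres were passaged on day 29 and alveolar spheres on day 26. At day 41 they were dissociated, sorted for viable cells by exclusion of DAPI, and loaded for droplet-based 3′ single-cell RNA sequencing, in which each captured molecule carries a cell barcode and a unique molecular identifier (UMI). There was 1 library per medium.

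The authors deposited a single matrix of whole-number counts, the UMI count of each gene in each cell barcode, with no normalization. STAR, Cell Ranger and the human build hg19 are named per the submitters' processing notes. Their versions, settings and gene annotation are not given in the sources used here. The matrix held 32741 features, of which 32738 were Ensembl genes and 3 were reporter sequences (EGFP, MCHERRY and TDTOMATO), and 1456 barcodes. Each barcode ended in the number 1 (742 barcodes) or 2 (714 barcodes), and 0 barcode sequences occurred under both numbers. No label tied either number to a medium. The cells are therefore reported as library 1 and library 2, values are set side by side, and neither library is called proximal or distal. Gene symbols and Ensembl identifiers were taken from the deposited gene table. A genome and annotation of build hg19 were not used here, so no coordinates are given.

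Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept. This left 731 cells in library 1 and 698 in library 2. The 11 and 16 barcodes left out were all above the mitochondrial limit, and 1 and 2 of them also had too few genes. Kept cells held 30246809 UMIs in library 1 (8718 to 169770 per cell) and 20860364 in library 2 (6962 to 125221 per cell). Doublets were scored with Scrublet within each library. It called 1 cell of library 1 and 4 cells of library 2, and these were kept, with an alternative that left them out.

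For each library, or each cluster, UMIs of a gene were summed over cells and given as CPM, the count scaled to the total UMIs of that library or cluster, with the exact Poisson 95% interval of the sum. Folds are ratios of CPM with the exact 95% interval of a ratio of 2 counts. A fold against a count of 0 was computed against a floor of 3 counts per library (0.0992 CPM in library 1 and 0.144 CPM in library 2) and is written as "at least". Log2 differences are library 1 minus library 2 of CPM + 10, which understates differences of low genes. With 1 library per medium there was no test, no p-value and no standard error, and cells were not treated as replicates. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. All intervals and floors cover counting error only.

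Genes named between the libraries had at least 50 CPM on the higher side and at least 30 UMIs. The 12 with the largest and the 12 with the smallest log2 difference were taken, leaving out mitochondrial and ribosomal protein genes, MALAT1, NEAT1, sex-linked genes used for sample checks, and genes with only a clone name. To these were added 12 key genes (NKX2-1, SCGB3A2, SFTPC, SFTPB, SCGB1A1, TP63, FOXJ1, SOX2, SOX9, AFP, CDX2 and MKI67) and up to 4 members of each gene list with the highest CPM. Other list members, and the cluster levels singled out, were chosen after their values were seen.

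The 32 gene lists comprised 19 cell type lists (airway secretory, goblet or mucous, airway basal, multiciliated, neuroendocrine, alveolar type 2, alveolar type 1, lung progenitor, hepatic, intestinal, gastric, pancreatic or biliary, thyroid, neural, mesenchymal, endothelial, blood, pluripotent and cell cycle). The other 13 were gene group lists (Wnt target, Notch target and ligand, FGF response, BMP and TGF-beta response, glucocorticoid and cyclic AMP response, surfactant lipid and lamellar body, cholesterol synthesis, innate defence, interferon response, hypoxia and glycolysis, dissociation stress, unfolded protein response, and epithelial keratin and adhesion). Of 407 distinct listed genes, 3 symbols (CCN2, CXCL8 and PECAM1) were not in the gene table, where CTGF and IL8 stand for the first pair. For each list the median log2 difference was taken over members with at least 10 CPM in either library, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Some genes stand in more than 1 list: SFTA3, SOX9, SOX2, KRT19, KRT7, ID2, ETV5, LPCAT1, SLPI and TFF3 are examples.

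Cells of both libraries were clustered together. UMIs were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were used after leaving out every listed gene, mitochondrial and ribosomal protein genes and sex-linked genes, followed by 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 with seed 0. Listed genes did not enter the clustering, but genes that rise with them may have, and the cluster names rest on listed genes. High levels of a class's markers in the cluster named for it are therefore not independent support for the name. Clusters were named from the fixed cell type markers among the 10 genes leading each cluster by fold, with at least 3 markers of the class detected. The names were assigned by hand after the leading genes were seen. Cluster 10 was called intestinal-like from CDX2 and FABP2, with TFF2 of the gastric list also among its leading genes. Cluster 1 had LPCAT1 and SFTPC of the alveolar type 2 list and markers of other lists among its leading genes. It was left unnamed although the alveolar type 2 list held the most, because genes outside that list, with SST, most of whose UMIs lay in 1 cell, at the top, led it. Some results for single genes are left out of the text. Cluster 4 had markers of the basal, alveolar type 2 and secretory lists and was left unnamed, as were clusters 8 and 9, with no marker there, and cluster 11, with CAV1 alone.

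Shares of cells with a UMI of a gene were compared after thinning each cell at random to 5000 UMIs. No kept cell was shallower. Shares are means over 20 draws, and the unthinned share is given beside them. The calculation of folds and intervals was tested on simulated library sums for library 1 against library 2 over 32741 genes. The sums were drawn from the Poisson model that the intervals assume, and no cells were simulated. This checks the calculation and not whether that model holds for these data. Planted folds of 1.5, 2, 4 and 8 were recovered as 1.49, 1.99, 3.98 and 7.86 (50 genes each). Intervals were scored against the CPM ratio that the planted folds and the simulated totals give, which is not exactly the planted fold. They held that ratio for 92%, 96%, 96% and 96% of genes. For 14042 unchanged genes they held it in 95.8%, with a median recovered ratio of 0.979.

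The lists, cell filter, clustering settings, key genes and most alternatives were chosen before the data were examined. Those alternatives were: all barcodes kept; at least 1000 genes and at most 10% mitochondrial UMIs; doublets left out; the mean over cells of each cell's CPM; TMM scaling factors from edgeR; a pseudocount of 1; thinned counts; all list members with at least 1 UMI; 4000 variable genes; 15 components; resolutions of 0.3 and 1.0; listed genes kept; clustering on a random portion of the UMIs and measuring on the rest; seed 1; thinning to 2000 UMIs or not at all; and at least 2 UMIs per cell. Added after seeing the data were: leaving out the hepatic-like, gastric-like and intestinal-like clusters; leaving out the cell with most UMIs of each gene from a library or a cluster; and leaving out clusters 8 and 9. TMM scaling (factors 1.05 and 0.955) shifted every log2 difference by -0.13 before the pseudocount and moved the median from 0.31 to 0.16 over genes with at least 50 CPM in either library, mitochondrial and ribosomal protein genes included.

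Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.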

Results

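Single-cell transcriptomes were measured at day 41 in lung epithelial spheres grown from NKX2-1 GFP-positive progenitors of the human induced pluripotent stem cell line BU3 NGST. There was 1 library from an airway (proximal) medium and 1 from an alveolar (distal) medium, and the study title sets bronchospheres against alveolospheres with attention to SCGB3A2, a secretoglobin of airway secretory cells. The barcodes separate 2 libraries that no label ties to a medium, so library 1 and library 2 are described side by side. After filtering, library 1 held 731 cells and library 2 held 698. The median cell had 36149 UMIs and 5152 genes in library 1, and 25606.5 UMIs and 3990.5 genes in library 2. Median mitochondrial shares were 5.66% and 5.49%. Ribosomal protein genes took 33.1% of the UMIs of library 1 and 42.9% of those of library 2, and MALAT1 took 1.72% and 3.03%. With 1 library of each kind, no difference has a replicate check, and every interval covers counting error only.

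The first comparison asked which genes differed between the 2 libraries. Library 1 carried abundant transcripts of liver-type secreted proteins alongside airway genes. ALB (ENSG00000163631), the main plasma protein, stood at 7635 CPM in library 1 and 0.719 CPM in library 2, a 10617-fold ratio (95% interval 6437 to 18970). On the log2 scale library 2 was led by the trypsinogen gene PRSS1 (ENSG00000204983), at 428 CPM against 12.7 CPM, a 33.6-fold ratio (30.4 to 37.3). NKX2-1 (ENSG00000136352), the lung and thyroid lineage transcription factor whose reporter had been used to select the progenitors, was 2.21-fold higher in library 2 (106 against 47.8 CPM, interval 2.07 to 2.36).

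Among the 2210 genes with enough UMIs to be named, 313 were at least 2-fold higher in library 1 and 99 in library 2 on the log2 scale, around a median log2 difference of 0.34. Most of the 12 genes with the largest log2 differences (of CPM + 10) towards library 1 encode proteins secreted by hepatocytes or fetal liver. They included APOA2 (6232 against 8.82 CPM, 707-fold) and APOA1 (1394 against 4.79 CPM, 291-fold), apolipoproteins of high-density lipoprotein, and TTR (3203 against 2.30 CPM, 1392-fold), the thyroxine carrier transthyretin. AFP, the fetal albumin, was at 2635 against 3.84 CPM (687-fold). FGB, a fibrinogen chain, was at 846 against 0.479 CPM (1765-fold), AMBP, the precursor of a plasma protease inhibitor, at 1316 against 8.92 CPM (148-fold), and SERPINA1, alpha-1-antitrypsin, at 7042 against 142 CPM (49.5-fold). FABP1, the liver fatty acid binding protein, was at 535 against 1.68 CPM (319-fold). IGF2, a fetal growth factor, was at 2676 against 52.9 CPM (50.6-fold), and NTS, the gut peptide neurotensin, at 1079.5 against 2.78 CPM (388-fold). SPP1, the secreted phosphoprotein osteopontin, had 498 CPM in library 1 and 0 UMIs in library 2, at least 3465-fold higher. The hepatic-like, gastric-like and intestinal-like clusters described later carried most of the library 1 UMIs of these genes. Without them the 12 genes kept their direction at lower levels in library 1: APOA2 was at 201 CPM (253-fold), TTR at 126 CPM (122-fold), APOA1 at 67.5 CPM (48.1-fold) and SERPINA1 at 192 CPM (8.35-fold). AMBP was then at 46.4 CPM (15.5-fold), NTS at 60.2 CPM (21.4-fold), IGF2 at 471 CPM (8.63-fold), FGB at 73.9 CPM, FABP1 at 13.7 CPM and SPP1 at 16.5 CPM, these last with 0 UMIs in library 2 (at least 404-fold, 74.8-fold and 89.96-fold). ALB was at 1046 CPM (3426.5-fold) and AFP at 184 CPM (752-fold). These remaining levels may hold free RNA, released by the cells left out and caught with other cells. APOA2 was at 174 CPM in airway secretory-like cells and 157 CPM in cluster 4, against 13658 CPM in hepatic-like cells. TTR was at 132 and 118 CPM, against 6928 CPM. The folds without those clusters therefore do not show that the remaining cells transcribed these genes.

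Towards library 2, the genes after PRSS1 were a second trypsinogen, PRSS3 (134 against 2.64 CPM, 50.5-fold), TUBB2B, a beta-tubulin of immature neurons and other progenitors (219 against 4.00 CPM, 54.7-fold), and PCP4, a calmodulin regulator (171 against 2.45 CPM, 69.7-fold). PRSS1 and PRSS3 are near-identical paralogs, so UMIs may have been split between them in counting. CRABP2, a retinoic acid binding protein, stood at 493 against 47.4 CPM (10.4-fold), and CADM1, an adhesion molecule, at 429 against 43.2 CPM (9.92-fold). CLDN18, a claudin of stomach and lung, was at 137 against 8.43 CPM (16.2-fold), LYZ, lysozyme, at 168 against 16.1 CPM (10.5-fold), and WFDC2, a secreted protein of airway epithelium, at 796 against 124 CPM (6.40-fold). SLC2A3, a glucose transporter, was at 89.3 against 3.93 CPM (22.7-fold) and TXNIP, a brake on glucose uptake, at 135 against 11.9 CPM (11.4-fold). SST, the peptide hormone somatostatin, was at 50.3 CPM against 0 UMIs (at least 507-fold), but its log2 difference of -2.59 was -0.25 without the cell that held the most SST UMIs. LYZ also depended on the hepatic-like, gastric-like and intestinal-like clusters: its log2 difference of -2.77 was -0.87 without them. There CLDN18 was at 32.6 against 0.265 CPM, PRSS1 at 217 against 0.596 CPM and TUBB2B at 272 CPM against 2 UMIs, a ratio of 2053 (568 to 16956). PRSS3 was at 85.3 CPM against 0 UMIs (at least 429.6-fold) and CADM1 was 15.7-fold higher in library 2. The folds of PCP4 (44.99), SLC2A3 (14.3), TXNIP (7.06) and CRABP2 (6.86) were smaller than in all cells.

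Among the key lung genes, secretory transcripts were higher in library 1 and the distal surfactant gene SFTPC was higher in library 2. SCGB3A2 (ENSG00000164265) stood at 303 CPM in library 1 and 47.9 CPM in library 2 (6.33-fold, 5.93 to 6.76). SFTPB (ENSG00000168878), a surfactant protein made in alveolar type 2 and some airway cells, stood at 1019 and 326 CPM (3.13-fold, 3.05 to 3.21). SFTPC (ENSG00000168484), the surfactant protein specific to alveolar type 2 cells and their distal progenitors, was at 8.43 CPM in library 1 and 37.8 CPM in library 2 (4.49-fold, 3.89 to 5.19). TP63, the transcription factor of basal cells, had 410 UMIs in library 1 (13.6 CPM) and 1 in library 2 (0.0479 CPM), a ratio of 283 (50.5 to 11196). SCGB1A1, the secretoglobin of mature club cells, had 167 UMIs (5.52 CPM) and 1 UMI, a ratio of 115 (20.4 to 4576), and the intestinal transcription factor CDX2 had 160 and 1, a ratio of 110 (19.5 to 4385). SOX2, of proximal airway progenitors, was 2.23-fold higher in library 2 (81.5 against 36.6 CPM) and SOX9, of distal tip progenitors, 2.00-fold higher (40.3 against 20.1 CPM). MKI67, a proliferation marker, was 1.60-fold higher in library 1 (38.9 against 24.3 CPM), but cell cycle genes did not share that direction. Of the 4 with the highest CPM, UBE2C (1.89-fold), TOP2A (1.43-fold) and HMGB2 (1.36-fold) were higher in library 2 and TYMS (1.52-fold) in library 1. FOXJ1, the regulator of motile cilia, was at 4.10 and 5.08 CPM, a ratio of 1.24 with an interval that includes no difference (0.947 to 1.62). Without the hepatic-like, gastric-like and intestinal-like clusters FOXJ1 was at 0.596 and 6.17 CPM, 10.4-fold higher in library 2 (5.24 to 23.3).

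**Figure D1:**
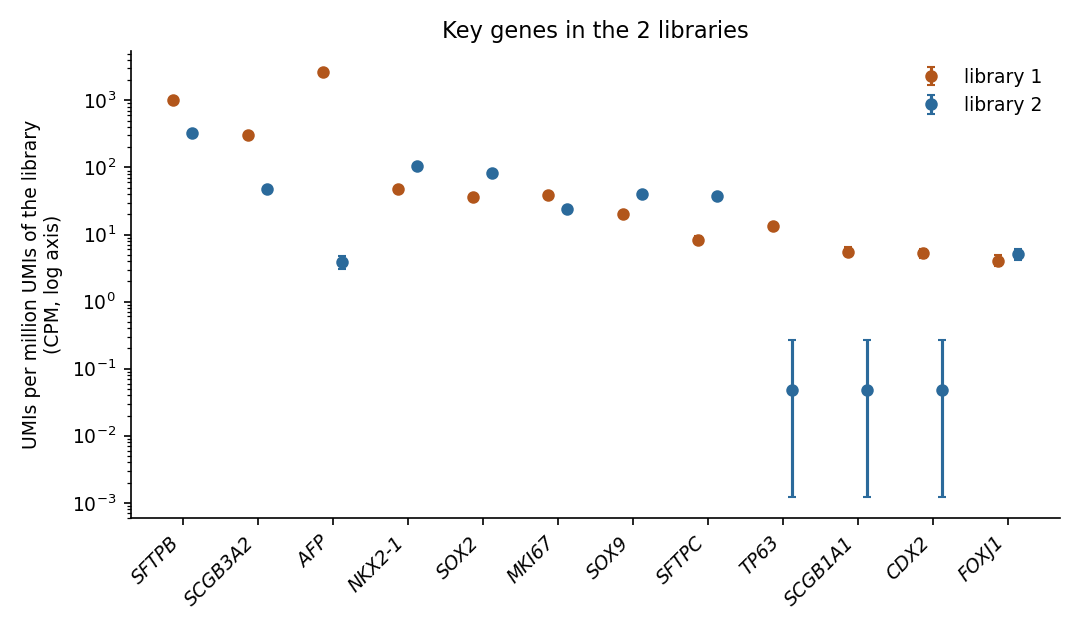
Scaled UMI counts (CPM, log axis) of the 12 key genes summed over the kept cells of library 1 (orange, 731 cells) and library 2 (blue, 698 cells); bars are exact Poisson 95% intervals, which cover counting error only and are mostly smaller than the points. TP63, SCGB1A1 and CDX2 have 1 UMI each in library 2 (0.0479 CPM), AFP differs from 2635 to 3.84 CPM, and the FOXJ1 intervals overlap.

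Few cells set some of these sums. A single cell held 32.9% of the SFTPC UMIs of library 1, another held 22.9% of those of library 2, and 35.3% of SCGB1A1 UMIs in library 1 came from 1 cell. Without the cell with most UMIs of the gene, APOA2 in library 2 was at 1.49 CPM in place of 8.82 CPM and FABP1 at 0.0481 CPM in place of 1.68 CPM. When each cell counted alike (the mean over cells of each cell's CPM), the log2 difference of SFTPC was -0.45 in place of -1.38, that of SCGB3A2 was 3.33 in place of 2.43 and that of SFTPB was 2.80 in place of 1.62. The pseudocount also mattered for SFTPC, whose difference was -2.04 with 1 CPM added in place of 10.

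The hepatic list was higher in library 1. All 16 members were above 10 CPM in library 1, 15 of them were at least 2-fold higher there on the log2 scale and none in library 2, with a median log2 difference of 5.30 (percentile 100). The exception on that scale was HNF4A, the hepatocyte nuclear factor, at 11.9 against 0.959 CPM. The clotting factor chain FGA (194 against 0.240 CPM) and the lipoprotein gene APOB (133 CPM against 0 UMIs) followed the named genes. Without the hepatic-like, gastric-like and intestinal-like clusters the hepatic median was 3.07, HNF4A had 6 and 2 UMIs, a ratio of 3.25 (0.581 to 32.9), FGA had 261 and 1, a ratio of 283 (50.3 to 11216), and APOB was at 4.96 CPM against 0 UMIs. The levels left without those clusters may likewise hold free RNA. With a pseudocount of 1 the hepatic median over all cells was 7.12.

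Other endoderm lists divided between the libraries. The pancreatic or biliary list had a median of 1.34 (percentile 99.96), with 5 of 7 members at least 2-fold higher in library 1, led by SPP1, the ductal keratins KRT19 (1696 against 716 CPM) and KRT7 (261 against 71.0 CPM), and PROX1, a regulator of liver and pancreas development (53.2 against 9.49 CPM). Without the hepatic-like, gastric-like and intestinal-like clusters PROX1 turned direction, at 1.19 CPM in library 1 and 10.6 CPM in library 2 (8.92-fold, 5.48 to 15.4). The intestinal list had a median of 1.92 (percentile 99.8), with FABP1 and VIL1, the microvillus protein villin (46.6 against 4.99 CPM), 2 of its 3 measured members, higher in library 1. TFF3, a mucosal peptide of goblet cells, was the other member (100.5 against 133 CPM, or 15.8 against 158 CPM without those clusters), and the median was -0.73 without the hepatic-like, gastric-like and intestinal-like clusters. The gastric list had a median of -0.87 (percentile 0), with 3 of 8 members at least 2-fold higher in library 2, namely the gastric mucosal peptide TFF1 (663 against 136 CPM), CLDN18 and the gastric protease gene CTSE (28.0 against 3.84 CPM). The hormone gene GAST went the other way (49.6 CPM against 1 UMI). Without those clusters GAST was at 2.65 CPM against 0 UMIs, at least 14.5-fold higher in library 1, VIL1 was at 3.51 against 2.87 CPM, and TFF1 was at 2.05 CPM in library 1 and 18.8 CPM in library 2. The thyroid list rested on HHEX alone, a transcription factor also of liver (53.1 against 18.2 CPM, median 1.16, percentile 92.9), and its median was -0.84 without those clusters.

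Airway lists separated by cell type. The airway basal list was higher in library 1 with a median of 1.23 (percentile 99.99), and 5 of 9 members were at least 2-fold higher there and none in library 2. The basal keratins KRT6A (101 CPM) and KRT5 (32.0 CPM) had 0 UMIs in library 2, so they were at least 700-fold and 223-fold higher. S100A2, a calcium-binding protein of basal cells, stood at 36.5 against 1.97 CPM and COL17A1, a hemidesmosome collagen, at 14.7 against 0.192 CPM. The airway secretory list had a median of 2.09 (percentile 99.995), with 3 of 5 members at least 2-fold higher in library 1 and 1 in library 2. Its members higher in library 1 were SCGB3A2, the antiprotease SLPI (220 against 0.288 CPM, 764-fold) and the cytochrome P450 gene CYP4B1 (33.9 against 0.336 CPM), while WFDC2 was higher in library 2. The median over all 14 members with at least 1 UMI was 0.026. The summed CPM of the list went against its median, at 705 in library 1 and 853 in library 2. The goblet or mucous list had a median of -0.37 (percentile 2.30), with 1 of 5 members, the tetraspanin TSPAN8 (23.2 against 3.50 CPM, with 42.5% of its library 1 UMIs in 1 cell), at least 2-fold higher in library 2 and AGR2, a chaperone of mucin folding, at 464 against 438 CPM. In the cells outside the hepatic-like, gastric-like and intestinal-like clusters AGR2 was 2.07-fold higher in library 1 (469.6 against 227 CPM), and TSPAN8 had 14 UMIs in library 2 and 1 in library 1, a ratio of 12.9 (1.97 to 546). The multiciliated list had a median of -0.19 (percentile 15.9) over 3 members, of which TPPP3, a microtubule-associated protein, was at 38.2 against 10.4 CPM, with 48.7% of its library 1 UMIs in 1 cell, and at 47.3 against 0.331 CPM without those clusters. The multiciliated median was 0.047 over all members with at least 1 UMI, and the summed CPM of that list was 73.3 in library 1 and 67.6 in library 2. The neuroendocrine list was higher in library 2 (median -0.96, percentile 0.06), with 2 of 4 members at least 2-fold higher there, including CALCA, which encodes calcitonin and the calcitonin gene-related peptide (12.2 against 0.264 CPM, or 6.74 CPM in library 2 without the cell with most CALCA UMIs).

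By their medians, distal lung and progenitor lists leaned towards library 2, with exceptions. The alveolar type 2 list had a median of -0.75 (percentile 0), with 4 of 10 members at least 2-fold higher in library 2 and 3 in library 1. LPCAT1, an enzyme of surfactant phospholipid synthesis (354 against 56.2 CPM, 6.29-fold), the protease gene NAPSA (33.7 against 6.71 CPM) and SFTPC were among the first, and SFTPB, SFTPA1 (21.1 against 0.671 CPM) and SFTPA2 (30.4 against 0.144 CPM) were the second. SFTPA1 and SFTPA2, the surfactant protein A genes, are near-identical, so their separate counts are uncertain. The summed CPM of the alveolar type 2 list went against its median, at 1475 in library 1 and 1402 in library 2. The lung progenitor list had a median of -0.94 (percentile 0), with 5 of 15 members at least 2-fold higher in library 2 and none in library 1. CPM, which encodes the carboxypeptidase M used to sort lung progenitors, stood at 359 in library 2 against 59.6 in library 1 (6.02-fold), BMP4, a ligand of the distal lung tip, at 90.4 against 11.2 CPM (8.04-fold), and the transcription factor genes IRX2 at 79.8 against 10.2 CPM (7.81-fold) and FOXA2 at 117 against 34.9 CPM (3.37-fold). When the hepatic-like, gastric-like and intestinal-like clusters were left out, CPM stood at 453 against 39.98 (11.3-fold), while IRX2 was at 91.4 against 19.9 CPM (4.59-fold) and NAPSA at 42.7 against 13.3 CPM (3.21-fold). The alveolar type 1 list leaned the other way (median 0.71, percentile 99.5), with 4 of 9 members at least 2-fold higher in library 1 and 1 in library 2. HOPX (685 against 117 CPM) and the caveolin CAV1 (62.6 against 6.09 CPM) were examples of the first, and IGFBP2, an insulin-like growth factor binding protein, was the second (1747 against 682 CPM). The summed CPM of the alveolar type 1 list also went against its median, at 1694 in library 1 and 2011 in library 2.

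The hepatic-like, gastric-like and intestinal-like clusters together left 464 cells in library 1 and 558 in library 2 when taken out. NKX2-1 was then at 86.7 CPM in library 1 and 133.5 CPM in library 2 (1.54-fold, 1.44 to 1.65). SCGB3A2 was at 589 and 60.5 CPM (9.75-fold), and SFTPC at 16.6 and 47.2 CPM (2.84-fold). SOX9 was at 1.26 and 29.6 CPM, a 23.5-fold ratio (14.9 to 39.4) against 2.00-fold in all cells. TP63 had 402 UMIs and 1 UMI, a ratio of 436 (77.8 to 17252), SCGB1A1 had 163 and 0, and CDX2 had 0 in both. Other airway genes stood further above library 2 than in all cells. S100A2 was 33.4-fold, COL17A1 116-fold, CYP4B1 154-fold, KRT6A at least 1089.6-fold and KRT5 at least 346-fold higher in library 1. SFTPA1, of the alveolar type 2 list, also stood further above library 2 (48.4-fold). The medians of the airway secretory, airway basal, alveolar type 1, lung progenitor and alveolar type 2 lists were 2.86, 1.86, 1.20, -0.64 and -0.41.

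Among signalling lists, Wnt targets were higher in library 2 with a median of -0.96 (percentile 0), and 4 of 8 members were at least 2-fold higher there. TNFRSF19 (67.9 against 10.4 CPM) and ZNRF3, a feedback inhibitor of Wnt receptors (22.9 against 6.35 CPM), were examples, and LGR5, an R-spondin receptor, had 11.7 CPM against 0 UMIs, or 6.72 CPM against 0 without the hepatic-like, gastric-like and intestinal-like clusters. The Wnt antagonist DKK1 went the other way (149 CPM in library 1 against 3.31 CPM), but without those clusters it was at 4.70 and 1.34 CPM, 3.50-fold (2.14 to 5.93). BMP and TGF-beta response genes had a median of 0.88 (percentile 99.8), with 3 of 8 members at least 2-fold higher in library 1, among them ID4 (46.8 against 13.7 CPM), an inhibitor of differentiation factors, and BAMBI, a pseudoreceptor for BMP (27.9 against 4.60 CPM). Without those clusters that median was 0.17, and BAMBI turned direction, at 1.06 CPM in library 1 and 3.30 CPM in library 2 (3.11-fold, 1.76 to 5.83). Notch targets and ligands divided (median 0.54, percentile 92.9). HES4 (105 against 12.4 CPM) and the ligand JAG1 (50.3 against 8.10 CPM) were 2 of 6 higher in library 1, and the target HES1 was higher in library 2 (406 against 96.4 CPM). The summed CPM of the Notch list went against its median, at 315.5 in library 1 and 480 in library 2. FGF response genes had a median of 0.21 (percentile 66.7), with 0 of 9 members 2-fold apart, for example DUSP6 (61.8 against 86.8 CPM). Glucocorticoid and cyclic AMP response genes had a median of 0.33 (percentile 84.7), with 2 of 11 at least 2-fold higher in library 1, namely FKBP5, a co-chaperone of the glucocorticoid receptor (59.5 against 9.54 CPM), and ZBTB16 (21.0 against 2.11 CPM).

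Hypoxia and glycolysis genes were higher in library 2, with 11 of 13 members at least 2-fold higher there and none in library 1 (median -1.49, percentile 0). They included the glycolytic enzymes PGK1 (657 against 162 CPM) and LDHA (985 against 344 CPM), SLC2A3, and the carbonic anhydrase CA9 (40.5 against 0.529 CPM, 76.6-fold). The median was -2.13 with a pseudocount of 1. Innate defence genes were higher in library 1 (7 of 8 at least 2-fold, median 1.69, percentile 100), with SLPI, the chemokine CCL20 (283 against 17.6 CPM), the complement component C3 (49.99 against 2.54 CPM) and the elastase inhibitor PI3 (23.9 CPM against 0 UMIs) as examples. The other member, the chemokine CXCL2, was at 34.9 CPM in library 1 and 74.3 CPM in library 2. Without the hepatic-like, gastric-like and intestinal-like clusters that median was -0.45, and CCL20 was at 13.6 CPM in library 1 and 22.2 CPM in library 2. Interferon response genes had a median of 0.60 (percentile 97.3), 2 of 4 being at least 2-fold higher in library 1, such as ISG15, an interferon-induced ubiquitin-like protein (28.4 against 7.86 CPM), and 1, CD74, in library 2 (18.7 against 2.45 CPM). Without those clusters the interferon median was 0.07 and ISG15 was 2.02-fold higher in library 1. There CD74 had 329 UMIs in library 2 and 3 in library 1, a ratio of 101 (34.3 to 493), and CA9 had 312 and 1, a ratio of 288 (51.3 to 11406).

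The dissociation stress list had a median of -0.59 (percentile 0) and 2 of 13 members at least 2-fold higher in library 2, for example JUN (526 against 151 CPM). HSPB1 went the other way, at 276 CPM in library 1 and 209 CPM in library 2. Lipid synthesis lists differed little. The surfactant lipid and lamellar body list had a median of -0.24 (percentile 0.57), with LPCAT1 higher in library 2 and ACSL4, an acyl-CoA synthetase, higher in library 1 (63.9 against 10.6 CPM). The cholesterol synthesis list had a median of -0.30 (percentile 0.185), with 0 of 13 members 2-fold apart, for example SQLE (178 against 109 CPM). The unfolded protein response list had a median of -0.15 (percentile 2.86) and 1 of 11 members at least 2-fold higher in library 1. HSPA5, the main chaperone of the endoplasmic reticulum, stood at 246 against 162 CPM. The cell cycle list had a median of 0.14 (percentile 31.1) and 1 of 15 members 2-fold apart, and was -0.022 without the hepatic-like, gastric-like and intestinal-like clusters and -0.025 without clusters 8 and 9. Its summed CPM was 857 in library 1 and 901 in library 2. Simple epithelial keratins KRT8 (1975 against 553 CPM) and KRT18 (2004 against 761 CPM) were higher in library 1, while CLDN4, a tight junction claudin, was higher in library 2 (218 against 98.1 CPM). The whole epithelial keratin and adhesion list had 4 of 12 members at least 2-fold higher in library 1 and 2 in library 2 (median 0.44, percentile 85.1, or -0.077 without those clusters). Also without them, ACSL4 was 2.15-fold and KRT18 1.62-fold higher in library 1.

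Markers of non-epithelial cells were scarce. The neural list rested on MAP2 (11.97 and 12.3 CPM, median -0.02, percentile 37.3). The mesenchymal list had a median of -0.40 (percentile 8.97) over 2 members, COL1A1 (3.31 and 22.8 CPM) and ACTA2 (10.9 and 4.84 CPM), and of 0.011 over all members with at least 1 UMI. The endothelial list had a median of -0.82 (percentile 1.46) over CLDN5 (0.198 and 10.7 CPM, with 47.8% of its library 2 UMIs in 1 cell) and EGFL7 (31.6 and 53.8 CPM), and the blood list a median of -1.50 (percentile 0.31) over LYZ and CD68 (9.62 and 12.8 CPM). LYZ is also made by gastric epithelium. No pluripotent gene reached 10 CPM, the highest being L1TD1 (5.22 and 7.09 CPM). With the hepatic-like, gastric-like and intestinal-like clusters left out, L1TD1 was at 1.32 and 8.12 CPM, EGFL7 at 15.6 and 44.4 CPM and CLDN5 at 0.397 and 13.6 CPM, and the CD68 ratio of 1.22 had an interval that includes no difference (0.8096 to 1.85).

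The second question was which kinds of cells the libraries held. Clustering of the pooled cells without any listed gene gave 11 clusters. The 2 libraries hardly mixed: 1427 of 1429 cells (99.86%) lay in a cluster whose other cells were mainly from their own library. With 1 library per group, a cluster made mostly of 1 library may be that library and not a cell type. Hepatic-like cells (cluster 2) made up 32.7% of library 1 (239 of 731 cells, 29.3 to 36.2%), airway basal-like cells (cluster 3) 23.4% (171 cells, 20.4 to 26.6%), airway secretory-like cells (cluster 7) 16.3% (119 cells, 13.7 to 19.2%) and intestinal-like cells (cluster 10) 3.83% (28 cells, 2.56 to 5.49%, plus 1 cell of library 2). In library 2, gastric-like cells (cluster 6) made up 19.9% (139 of 698 cells, 17.0 to 23.1%) and cycling cells (cluster 5) 19.9% (139 cells, plus 1 cell of library 1).

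The remaining clusters stayed unnamed. Cluster 4 (156 cells, 21.3% of library 1) was led by markers of basal, secretory and alveolar type 2 cells, which does not place them in the same cells. There SCGB3A2 and TP63 met in 1.30 cells (mean over draws) at equal depth, where the product of the 2 shares gives 4.53. Without thinning these numbers were 34 and 41.4. Cluster 11 (17 cells, 2.33%) had few detected genes (median 1503). Cluster 1 (265 cells, 38.0% of library 2) was led by SST and markers of several lung classes, cluster 8 (89 cells, 12.8%) by SLC2A3, with BNIP3 and SLC2A1 of the hypoxia and glycolysis list also among its 10 leading genes, and cluster 9 (65 cells, 9.31%) by MAFF. The 10 leading genes of cluster 9 included ADM and VEGFA of the hypoxia and glycolysis list and ATF3 of the dissociation stress list. The basal-like share was sensitive to settings, being 44.7% at resolution 0.3 and 41.7% with the listed genes kept in the clustering.

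**Figure D2:**
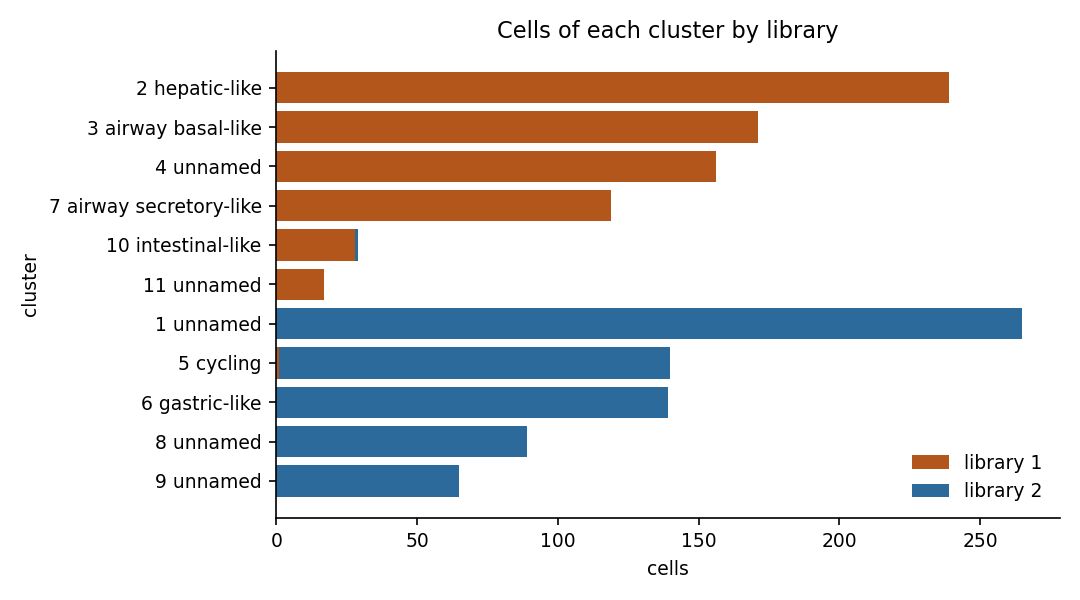
Number of cells (horizontal axis) in each of 11 clusters of the pooled cells, coloured by library (orange, library 1; blue, library 2). Clusters are nearly all of 1 library: 1 cell of library 2 lies in the intestinal-like cluster 10 and 1 cell of library 1 in the cycling cluster 5.

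Within library 1, NKX2-1 was higher in clusters 3, 4 and 7 than in hepatic-like and intestinal-like cells, but liver and lung genes were not fully apart. Hepatic-list genes summed to 7961 CPM in the airway secretory-like cells, where ALB and FGG were high, as described below. The airway secretory-like cells had SFTPB at 8866 CPM, SCGB3A2 at 2042 CPM, SLPI at 1043 CPM and NKX2-1 at 219 CPM, which was 10.0 CPM in hepatic-like cells and 0 UMIs in intestinal-like cells. The same cells had FASN, the fatty acid synthase, at 746 CPM and the water channel AQP4 at 202 CPM. Their alveolar type 2 list, which includes SFTPB, summed to 11319 CPM, above their airway secretory list at 4173 CPM. The basal-like cells and cluster 4 shared TP63 (35.8 and 27.6 CPM), KRT5 (74.2 and 77.9 CPM) and KRT6A (243 and 225 CPM), while SCGB3A2 summed to 18.6 CPM in the first and 708 CPM in the second, and MKI67 at 2.66 and 93.8 CPM. The basal-like MKI67 level depended on the clustering: it was 27.1 CPM when clusters were made on a random portion of the UMIs and measured on the rest. A minority of cells carried the SCGB3A2 of cluster 4, where the median cell was at 19.5 CPM and the 90th percentile at 914 CPM, and the median airway secretory-like cell was at 158 CPM. Without the cell with most KRT5 UMIs, KRT5 was at 49.5 and 52.5 CPM in the basal-like cells and cluster 4. Few cells carried it: without thinning, 11 of 171 basal-like cells and 26 of 156 cells of cluster 4 had a KRT5 UMI. The basal-like cluster was led by CSTA, with KRT13 (891 CPM) also among its 10 leading genes. SOX9 stood between 0.465 and 1.45 CPM in these 3 lung clusters and at 40.3 CPM in the hepatic-like cells. Hepatic-like cells also carried most CCL20 (613 CPM), a chemokine. The intestinal-like cells had CDX2 at 93.0 CPM together with TFF1 at 2414 CPM and AGR2 at 3103 CPM, or 2053 CPM without the cell with most AGR2 UMIs. Their gastric list summed to 3611 CPM, above their intestinal list at 1568 CPM, which stood at 1359 CPM in hepatic-like cells.

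Within library 2, NKX2-1 stood at 148 CPM in cluster 1, 142 CPM in the cycling cells and 104 CPM in cluster 8, against 3.84 CPM in gastric-like cells. SFTPC was at 64.1 and 48.9 CPM in cluster 1 and the cycling cells, and at 39.4 and 37.7 CPM without the cell that held the most SFTPC UMIs in each. The airway secretory-like cells of library 1 stood higher, at 114 CPM, or 75.2 CPM without such a cell. The carboxypeptidase M gene stood at 518 and 560 in the same unit in cluster 1 and the cycling cells. Gastric-like cells carried TFF1 at 3053 CPM, LYZ at 756 CPM, CLDN18 at 524 CPM and SOX9 at 79.7 CPM. The cycling cells had TOP2A, a topoisomerase of dividing cells, at 335 CPM, and MKI67 at 77.0 CPM against 4.70 CPM in cluster 1. Summed hypoxia and glycolysis genes ranged from 2430 CPM in gastric-like cells to 9530 CPM in cluster 8, and from 890 to 1425 CPM across the clusters of library 1.

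**Figure D3:**
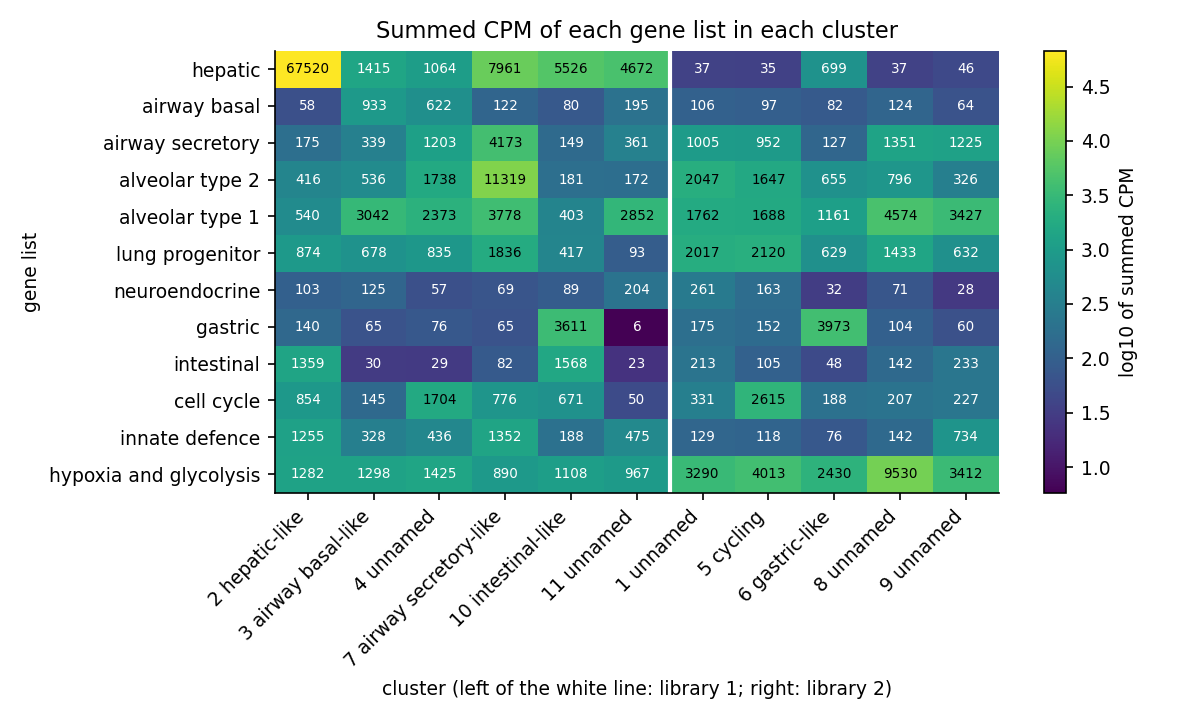
Summed CPM of 12 gene lists (vertical axis) in each of 11 clusters (horizontal axis, library 1 left of the white line and library 2 right of it), printed in each field and coloured by its log10; no intervals are drawn. The hepatic list reaches 67520 CPM in hepatic-like cells and 7961 CPM in airway secretory-like cells, 5526 CPM in intestinal-like cells and 4672 CPM in cluster 11, against 1415 and 1064 CPM in clusters 3 and 4. The gastric list reaches 3973 CPM in gastric-like cells and 3611 CPM in intestinal-like cells, whose intestinal list is at 1568 CPM. The hypoxia and glycolysis list spans 2430 to 9530 CPM over the clusters of library 2 and 890 to 1425 CPM over those of library 1.

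ALB and the fibrinogen chain FGG were also high outside the hepatic-like cells. In airway secretory-like cells ALB stood at 5158 CPM, against 15851 CPM in hepatic-like cells, 453 CPM in basal-like cells, 254 CPM in cluster 4, 290 CPM in intestinal-like cells and 676 CPM in cluster 11 (272 CPM without the cell with most ALB UMIs). FGG stood at 1312 CPM in airway secretory-like cells, above the 523 CPM of hepatic-like cells. Clustering on a random portion of the UMIs and measuring on the rest gave ALB at 2777 CPM in airway secretory-like and 15783 CPM in hepatic-like cells. That airway secretory-like class did not hold the same cells. SFTPB and NKX2-1 were lower in it as well, at 6465 and 159 CPM against 8866 and 219 CPM. Other liver genes were closer to cluster 4. FGB was at 179 CPM against 28.7 CPM in cluster 4, AFP at 428 against 124 CPM, RBP4, a retinol carrier, at 56.7 against 6.46 CPM and FGA at 40.9 against 10.3 CPM, each under 10% of the hepatic-like level above cluster 4. APOA2 was at 174 CPM in airway secretory-like and 13658 CPM in hepatic-like cells, and SERPINA1 at 252 and 15442 CPM.

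**Figure D4:**
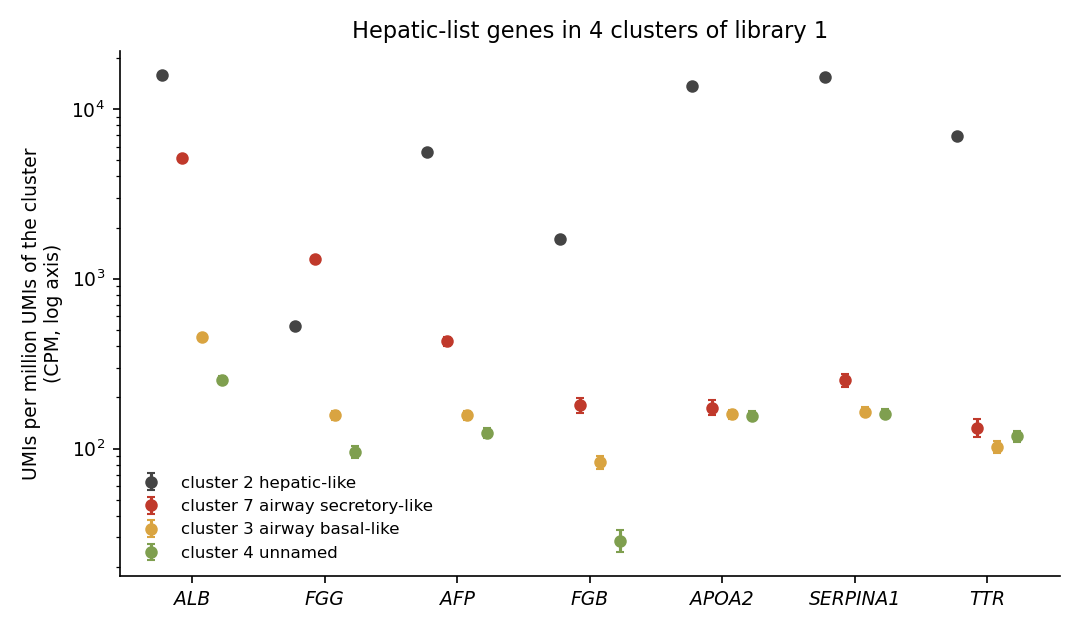
CPM (log axis) of 7 hepatic genes in 4 clusters of library 1: hepatic-like (239 cells), airway secretory-like (119 cells), airway basal-like (171 cells) and the unnamed cluster 4 (156 cells); bars are exact Poisson 95% intervals, which cover counting error only. ALB (5158 CPM) and FGG (1312 CPM) in airway secretory-like cells lie well above the basal-like cells and cluster 4, while APOA2 (174 CPM) and TTR (132 CPM) lie near them.

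The third question was what share of cells carried each key transcript at equal depth. NKX2-1 was detected in 23.7% of library 1 cells (20.7 to 27.0%) and 36.4% of library 2 cells (32.8 to 40.0%) at 5000 UMIs per cell, and in 60.6% and 71.3% without thinning. By cluster it was highest in airway secretory-like cells (62.2%, median depth 15009 UMIs), cluster 1 (50.2%, 24483 UMIs) and cycling cells (48.0%, 37500 UMIs). The hepatic-like cells had 4.94% (28.0% unthinned, median depth 53299 UMIs), the gastric-like cells 2.05% (27804 UMIs), and the intestinal-like cells 0 of 29, which allows a share of cells with a UMI of up to 10.3%. Whether the hepatic-like share is background alone cannot be told. Without thinning, 32 of those cells had both NKX2-1 and its reporter EGFP, against 13.5 from the product of the shares. Deeper cells detect more of both genes, which raises the count above the product. At equal depth the numbers (0.900 and 0.291 cells) were too small to decide. Median depths were 35635 UMIs in basal-like cells and 38910 UMIs in cluster 4. SCGB3A2 was detected in 19.2% of library 1 and 8.74% of library 2 (50.8% and 22.5% unthinned). Its share was 56.2% in airway secretory-like cells and 26.9% in cluster 4, against 6.82% in hepatic-like and 1.12% in gastric-like cells. The 7.08% of basal-like cells with SCGB3A2 lay within counting error of the hepatic-like share. This does not show that it is background, since the hepatic-like share may not be background alone. A single cell held 27.7% of the basal-like SCGB3A2 UMIs. In library 2, cluster 1 had 10.9% and the cycling cells 11.7%, above the gastric-like share.

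SFTPC was detected in 2.46% of library 1 and 6.42% of library 2 (5.34% and 16.0% unthinned). Its share was 14.0% in airway secretory-like cells, 10.2% in cycling cells and 9.43% in cluster 1, against 0.105% in hepatic-like and 1.83% in gastric-like cells. SFTPB was near universal in airway secretory-like cells (97.1%), but 25.2% of hepatic-like cells also had a UMI, and the 26.2% of basal-like cells lay within counting error of that share. In library 2 it was detected in 48.6% of cluster 1 and 49.5% of cycling cells, against 6.94% of gastric-like cells. TP63 was detected in 15.5% of basal-like cells and 10.8% of cluster 4 (60.2% and 45.5% unthinned), against 0.272% of hepatic-like cells (2.93% unthinned). SCGB1A1 was detected in 4.202% of airway secretory-like cells (5.88% unthinned) against 0.0628% of hepatic-like cells, and 62.8% of its UMIs in the former came from 1 cell. FOXJ1 did not exceed 4.09% in any cluster (cluster 1), with 3.81% in hepatic-like cells.

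SOX2 was detected in 18.4% of library 1 and 30.1% of library 2 (58.8% and 70.5% unthinned), with 39.4% in cluster 1 and 6.76% in hepatic-like cells. SOX9 was detected in 6.61% and 16.0% (24.4% and 45.3% unthinned), led by gastric-like cells at 29.2%, and in 0.336% of airway secretory-like cells. CDX2 was detected in 36.6% of intestinal-like cells (86.2% unthinned) and 0.272% of hepatic-like cells. MKI67 was detected in 31.6% of cluster 4 and 29.0% of cycling cells, against 1.08% of basal-like cells and 1.42% of cluster 1. AFP was detected in 99.3% of hepatic-like cells, and AFP UMIs were widespread in library 1: 48.4% of basal-like cells and 45.3% of cluster 4 had a UMI at 157 and 124 CPM, against 5545 CPM in hepatic-like cells. AFP was higher in intestinal-like cells (91.6%, 1122 CPM) and airway secretory-like cells (62.2%, 428 CPM), and cluster 11 had 38.8% at 227 CPM, or 100.2 CPM without 1 cell. How much of the AFP outside hepatic-like cells was free RNA was not tested.

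The last question was whether the airway transcript SCGB3A2 and the alveolar transcript SFTPC met in the same cells. In library 1, 9.45 cells (mean over draws, 1.29%, 0.606 to 2.40%) had a UMI of both at equal depth, where the product of the 2 shares gives 3.44 cells. Without thinning 28 cells had both, against 19.8. In library 2, 5.85 cells (0.838%, 0.303 to 1.83%) had both against 3.91 from the product, and 39 against 25.2 without thinning. At equal depth nearly all such cells of library 1 lay in the airway secretory-like cluster, and within it 9.40 cells had both where the product gives 9.40. Within cluster 1 the numbers were 3.70 and 2.73 cells, and in the cycling cells 2.10 and 1.67. Without thinning they were 22 and 15.3 in cluster 1, 16 and 11.4 in the cycling cells, and 23 and 23.2 in the airway secretory-like cluster. Cells are not replicates, so no p-value was computed, and these counts are small.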

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

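The tests on ALB, on hypoxia genes and on library preparation were chosen after the results were seen. EGFP, the reporter sequence, lies outside the gene comparisons and was above the limit that a count of 0 allows in both libraries, at 19.3 CPM in library 1 and 66.8 CPM in library 2. By cluster, EGFP stood at 79.9 CPM in airway secretory-like cells and 84.6 CPM in cluster 1, at 6.20 CPM in hepatic-like cells and 2.71 CPM in gastric-like cells, and had 0 UMIs in intestinal-like cells. MCHERRY and TDTOMATO had 0 UMIs in both libraries.

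ALB was high not only in hepatic-like cells (15851 CPM) but also in airway secretory-like cells (5158 CPM). It stood at 453 CPM in basal-like cells, 254 CPM in cluster 4, 290 CPM in intestinal-like cells and 676 CPM in cluster 11. When clusters were made on a random portion of the UMIs and measured on the rest, the airway secretory-like class had ALB at 2777 CPM. That class did not hold the same cells. Free RNA from hepatic-like cells would keep ALB and APOA2 in the ratio seen in other clusters, but the ratio was 29.7 here (26.8 to 33.0), 2.84 in basal-like cells, 1.62 in cluster 4 and 1.16 in hepatic-like cells. Droplets that also held a hepatic-like cell would bring the other 15 hepatic genes, but their median excess over cluster 4 was 1.34% of the hepatic-like level, against 30.9% for ALB and 232% for the fibrinogen gene FGG. A separate kind of cell without lung genes would lack NKX2-1. The 80 of 119 cells with high ALB had NKX2-1 at 218 CPM (193 to 245), against 10.0 CPM in hepatic-like cells, and SFTPB at 7867 CPM. These cells were picked by their ALB, which stood at 8581 CPM in them and 340 CPM in the other cells of the cluster. The test cannot exclude a separate kind of cell that has NKX2-1. ALB transcribed in NKX2-1-positive secretory-like cells may therefore be the source, a hypothesis found and examined on the same data, and no biological explanation was tested. The ratio to APOA2 and the choice of cells used ALB alone, so FGG was not examined in this way. NKX2-1 was summed over the 80 cells, so its presence with ALB in each cell was not shown.

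Hypoxia and glycolysis genes were higher in library 2. Scaling to total UMIs was argued against by TMM factors, under which the median log2 difference was -1.62. Free RNA from cluster 8 was argued against in gastric-like cells and cluster 1, where the leading gene of cluster 8 with the lowest share of its cluster 8 level stood at 1.79% and 6.44%, while the listed genes would need 18.4% and 15.7%. In the cycling cells (11.0%, with 19.2% needed) and cluster 9 (14.9%, with 26.2% needed) the lowest share lay over 0.5 of the need, so free RNA stays open there. Handling of the whole library cannot be told apart from culture: the lowest summed level in a cluster of library 2 was 2430 CPM and the highest in library 1 was 1425 CPM, and 1 library per medium, not tied to its medium, keeps this open, and no biological explanation was tested.

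The clusters divided by library almost completely. The depth gap was argued against because 99.86% of cells still lay with their own library after every cell was thinned to 5000 UMIs (10 clusters). Free RNA from hepatic-like and gastric-like cells was argued against because the share was 99.7% of 1051 cells without those cells and without 106 genes they could bring (9 clusters). Preparation of each library cannot be told apart from the medium, since the number of libraries per medium was 1. No biological explanation was tested.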

How the results depend on the processing

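Leaving out the hepatic-like, gastric-like and intestinal-like clusters, leaving out clusters 8 and 9, and leaving out the cell with most UMIs of each gene were chosen after seeing the data. Values are log2 differences, library 1 minus library 2, unless stated. With all barcodes kept, or with doublets left out, all 100 results compared under each setting kept their direction and stayed within their counting interval or, for counts, within 1.5 times. The clustering alternatives gave 9 to 13 clusters, with 99.7% to 99.93% of cells in a cluster of their own library. No paired analysis was possible because each medium has replicate number 1 alone, and no test was made. Where a value moved, the cause was not tested, except where a setting leaves out cells, genes or UMIs by construction.

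As the mean over cells of each cell's CPM, NKX2-1 was -0.52, SCGB3A2 3.33 and SFTPC -0.45. With each cell thinned to 5000 UMIs they were -0.73, 3.36 and -0.37. With TMM factors NKX2-1 was -1.11 and SCGB3A2 2.32, and the alveolar type 2, hepatic, and hypoxia and glycolysis lists were -0.86, 5.20 and -1.62. With a pseudocount of 1, NKX2-1 was -1.13, SCGB3A2 2.64 and SFTPC -2.04, and the airway secretory, alveolar type 2, hepatic, and hypoxia and glycolysis lists were 2.64, -0.84, 7.12 and -2.13. Over all members with at least 1 UMI the airway secretory, alveolar type 2, and hypoxia and glycolysis lists were 0.026, -0.24 and -1.43, and the multiciliated (0.047) and mesenchymal (0.011) lists turned direction.

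Without the hepatic-like, gastric-like and intestinal-like clusters NKX2-1 was -0.57, SCGB3A2 3.09 and SFTPC -1.10. The airway secretory, alveolar type 2, hepatic, and hypoxia and glycolysis lists were 2.86, -0.41, 3.07 and -1.57. The intestinal (-0.73), thyroid (-0.84), cell cycle (-0.022), innate defence (-0.45) and epithelial keratin and adhesion (-0.077) lists turned direction, and the blood list had no member left to give a value. The share with NKX2-1 was 34.8% of library 1 and 44.96% of library 2, and with SCGB3A2 26.2% of library 1. Without clusters 8 and 9 the alveolar type 2, hepatic, and hypoxia and glycolysis lists were -0.84, 5.19 and -1.24, and the cell cycle (-0.025) and unfolded protein response (0.14) lists turned direction.

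With at least 1000 genes and at most 10% mitochondrial UMIs the hepatic list was 5.37 and airway secretory-like cells were 20.3% of library 1, and with 15 principal components they were 20.9%. Airway basal-like cells were 44.7% of library 1 at resolution 0.3 and 41.7% with listed genes kept in the clustering.

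Shares of cells followed depth. Thinned to 2000 UMIs, NKX2-1 was in 11.8% and 18.1% of libraries 1 and 2, SCGB3A2 in 13.1% and 4.97% and SFTPC in 3.68% of library 2, with both SCGB3A2 and SFTPC in 4.90 and 1.95 cells. Not thinned, NKX2-1 was in 60.6% and 71.3%, SCGB3A2 in 50.8% and 22.5%, SFTPC in 5.34% and 16.0%, and both in 28 and 39 cells. With at least 2 UMIs, NKX2-1 was in 7.13% and 11.9%, SCGB3A2 in 10.7% and 3.72%, SFTPC in 1.14% and 2.64%, and both in 3.30 and 1.10 cells.

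Over all settings, list medians stayed within their intervals in 145 comparisons, moved in 93 and turned direction in 9. Gene differences stayed in 159 and moved in 156, shares of cells with a gene stayed in 90 and moved in 78, and class shares stayed in 38 and moved in 4. Depth limits what a count of 0 can show to 0.0992 CPM in library 1 and 0.144 CPM in library 2, and a single UMI per cell at 5000 UMIs cannot tell low expression from free RNA.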

Other observations

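The genes and clusters given here were chosen after their values were seen. Surfactant genes did not share a single pattern over the clusters. SFTPA1 and SFTPA2 were at 60.0 and 116 CPM in cluster 4 and at 112 and 68.3 CPM in airway secretory-like cells, but in cluster 1, where SFTPC was at 64.1 CPM (39.4 CPM without 1 cell), they were at 0.553 and 0.415 CPM. Without the cell with most UMIs of the gene, SFTPA1 and SFTPA2 were at 35.1 and 68.3 CPM in cluster 4 and at 69.5 and 28.4 CPM in airway secretory-like cells. SFTPC itself was at 0.323 CPM in cluster 4, and at 114 CPM in airway secretory-like cells (75.2 CPM without the cell with most SFTPC UMIs). The elastase inhibitor PI3 was at 197 CPM in airway secretory-like cells and 2.88 CPM in hepatic-like cells. FKBP5, a glucocorticoid target, ranged from 83.6 to 103 CPM in the basal-like cells, cluster 4 and airway secretory-like cells, and from 12.7 to 15.6 CPM in cluster 1 and the cycling cells.

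The chemokine genes of the innate defence list did not share a single pattern. CCL20 was at 613 CPM in hepatic-like cells and 281 CPM in cluster 9, IL8 at 257 and 218 CPM, and CXCL1 at 138 and 87.8 CPM, against 2.21, 22.0 and 11.9 CPM in cluster 1. Without the cell with most UMIs of the gene, CCL20 and IL8 were at 167 and 129 CPM in cluster 9. CXCL2 was at 37.4 CPM in hepatic-like cells, 138 CPM in cluster 9 and 85.4 CPM in cluster 1, CXCL5 at 16.5, 7.60 and 4.29 CPM, and CXCL6 at 46.3, 0.844 (1 UMI) and 0.829 CPM. Cluster 9 also had ATF3 at 134 CPM and JUND at 299 CPM, both of the dissociation stress list, with a median of 2338 genes per cell. The Wnt antagonist genes parted as well: DKK1 was at 325 CPM in hepatic-like cells and 0.968 CPM in cluster 1, and WIF1 at 104 and 161 CPM.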
